A study of Mus musculus with 6 samples.

How the data were processed

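RNA from the E16.5 LGE of 3 wild type and 3 Dlx1/2 mutant mouse samples on a mixed background of several strains was sequenced, and the results were given as 1 table with a line per gene and columns per library. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and edgeR, and the builds GRCm38.p4 and mm10, without saying which step each served. The deposited counts are whole numbers, raw read counts per gene per the file headers, and their totals per library run from 10711630 to 16588359. The FPKM values that the authors deposited beside them equal count per library total, up to a factor per gene that is the same in all libraries. In 11418 of 11418 genes with over 50 counts in every library, the ratio of count to FPKM per total was equal between libraries within 0.0001. That factor was not compared with gene length. A p-value per gene is also deposited, per the file headers, with no word on its test or on adjustment. The counter, the annotation release and any strand setting are not given in the sources used here.

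The table holds 21286 genes, none without a count, with a minimum of 2 counts over the 6 libraries. Of its gene IDs 21146, or 99.3%, were found in GENCODE M21 on GRCm38, which gave positions, the length and the GC content of the longest transcript. Spreadsheet software had turned 25 symbols into dates, and these were replaced through the gene ID. Columns were assigned to samples by the library names in the labels. All names of wild type libraries share a prefix and all mutant names share another, and the labels give no batch, so a batch that follows these names cannot be told apart from genotype. No replicate pair was alike within sampling noise, as the chi-square of their counts per degree of freedom was 7.60 to 15.3.

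Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, which left 15326, libraries were scaled by TMM, and the mutant was compared with wild type by the quasi-likelihood F test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.122. Levels are counts scaled to library size (CPM) after TMM normalisation, as mean ± SD over 3 libraries. The SE of a log2 fold change comes from the spread of log2 CPM between libraries with 0.5 added to each count. Where a group held 1 to 3 reads in all, the ratio is given with a 95% Clopper-Pearson interval of the reads of both groups. A floor of 3 counts corresponds to 0.181 to 0.280 CPM in a library. The authors' p-values were used only to count how many calls they share.

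Lists of marker and pathway genes, 27 lists with 379 distinct symbols of which 389 of 401 entries were found in the table, were fixed before the data were examined. They cover the Dlx family, GABA genes, olfactory bulb interneurons, striatal neurons, progenitors, other cell types that the tissue could hold, and signs of sample quality. Each list with at least 4 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, Dlx1 and Dlx2 left out. Of the 27 lists 12 passed, 7 lower and 5 higher; with an estimated correlation 0 did (limma camera), and with fry 16 did. At unadjusted p with the estimated correlation, the 12 lists ran from 0.00418 (shared striatal) to 0.287 (erythroid), 8 of them below 0.05. The genes named were drawn from Dlx1 and Dlx2, the 12 largest rises and 12 largest falls among called genes with groups apart, at least 5 CPM in the higher group and a symbol that is no clone name, and the up to 4 members of each list with the smallest adjusted p. The Dlx, GABA, olfactory bulb and striatal lists could be named in full. Where a list had no called member, the 2 with the highest level could be named. Besides Dlx1 and Dlx2 the rule gave 137 genes, 122 of them called. The text leaves out some of them, and this choice was made after the alternatives had been seen: the 16 called genes that lost the call under at least 1 alternative, the 2-fold minimum and the stricter threshold aside, are not named, so the genes named are steadier in those alternatives than those the rule gave. Genes that changed by less than 2-fold are named, 15 of them called. Among the uncalled genes of the rule, 6 changed sign and 3 gained a call under an alternative. A few genes outside the rule are named where the text says so.

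The alternatives were a fit with the replicate number of the labels as a factor, leaving out each library, RLE scaling, no filter on low counts, the Wald test of DESeq2 1.42.0, a 2-fold minimum, an adjusted p below 0.01, and for lists the estimated correlation, fry, and leaving out shared members. Thinning all libraries to the smallest total and a correction for GC content and length were added after the data had been seen. Settings meant for a table of normalised values alone were not run. The scripts were tested on simulated counts for the 15326 genes of this comparison with the real means and library sizes. Of the genes changed 1.5-fold, 62% were called with the right sign, of those changed 2-fold 88%, 4-fold 98% and 8-fold 100%. Of those calls 6.5% were unchanged genes. Of 20 unchanged lists 0 were called, but genes were drawn independently, so this does not check the preset correlation of the list test.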

Results

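RNA was sequenced from the lateral ganglionic eminence (LGE) of mouse embryos at embryonic day 16.5. The LGE is the part of the embryonic ventral forebrain whose progenitors give rise to striatal projection neurons and to interneurons of the olfactory bulb. The design held 3 libraries from wild type littermates and 3 from mutants lacking Dlx1 and Dlx2, a pair of homeobox transcription factors made by progenitors and young neurons of the ganglionic eminences. Total counts were 10711630, 15424167 and 16588359 in wild type replicates 1 to 3, and 16196974, 15670067 and 15895041 in mutant replicates 1 to 3. Replicates within a group correlated at Pearson's r of 0.9826 to 0.9901 across genes, and libraries of different genotype at 0.9562 to 0.9616. The labels do not say that each library came from a separate embryo, so p-values measure the spread between these libraries.

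The comparison asked which genes change in the LGE without Dlx1 and Dlx2, in a study concerned with how olfactory bulb interneurons are made. The targeted genes came first. Dlx2 (ENSMUSG00000023391, GRCm38 chromosome 2, 71543408 to 71546754, minus strand) was at 436.3 ± 29.8 CPM in wild type and at 16.8 ± 1.68 CPM in the mutant (mean ± SD, n = 3 each). Its log2 fold change was −4.70 ± 0.099 (SE) and its adjusted p = 1.14e-07. Dlx1 (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981, plus strand) went from 857.9 ± 35.7 to 122.1 ± 14.4 CPM, a log2 fold change of −2.81 ± 0.103 with adjusted p = 8.81e-07. The 3 mutant libraries held 109.3, 119.3 and 137.6 CPM of Dlx1 and 16.2, 15.5 and 18.7 CPM of Dlx2, each below every wild type library. An exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for each gene, the smallest value that it allows. The parts of the genes that the alleles remove are not given in the sources used here, and counts per gene do not separate reads of the remaining parts.

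The loss of Dlx1 and Dlx2 went with a wide change of the transcriptome. Of 15326 genes tested, 1715 were higher and 1958 lower in the mutant (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Among them 436 rose and 619 fell by at least 2-fold, and 44 rose and 83 fell by at least 8-fold. Among called genes with groups apart, at least 5 CPM in wild type and no clone name, the deepest fall was in Aldh1a3, an enzyme that makes retinoic acid, from 26.9 to 0.146 CPM (log2 fold change −7.45), followed by Dlx6os1, a long noncoding RNA of the Dlx5 and Dlx6 locus. Other large falls were in Cntnap3, a neuronal cell adhesion protein (−5.26), Rxrg, a retinoid X receptor (−5.09), Col6a1, a collagen chain (−6.27), and Sowaha (−5.01). Brs3, a bombesin-like receptor, had 266 reads over the wild type group and 3 over the mutant group, a ratio of 101 with a 95% counting interval of 34.0 to 491. All 3 mutant values lay on the same side of all 3 wild type values for 1708 of the higher and 1949 of the lower genes. This held for 41.9% of all tested genes, where chance gives 10%. In the authors' deposited table, 93.3% of the 3673 genes called here also had p below 0.05, and 2682 of them after Benjamini-Hochberg adjustment of that p (the sources used here do not say whether it is adjusted already). Of the called genes, 50% changed by less than 1.5-fold.

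Dlx5 and Dlx6, a pair of homeobox genes of the same family that lie beside each other on chromosome 6, fell along with the targeted genes on chromosome 2. Dlx5 fell from 170.8 ± 13.1 to 4.65 ± 1.02 CPM and Dlx6 from 70.0 ± 4.08 to 1.88 ± 0.586 CPM (n = 3), log2 fold changes of −5.20 ± 0.206 and −5.21 ± 0.244. Dlx6os1 fell from 680.4 ± 63.6 to 4.81 ± 0.978 CPM, and Dlx1as, the antisense transcript of Dlx1, by 2.13 on the log2 scale. Of the 4 tested family members besides the targets, 4 fell, also when adjusted over the list alone (camera adjusted p = 1.45e-06; adjusted p = 0.0541 with an estimated correlation). Whether reads were counted by strand is not given in the sources used here, so Dlx1as cannot be separated from Dlx1 nor Dlx6os1 from Dlx6.

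Genes that make and carry the inhibitory transmitter GABA fell too, by very different amounts. Slc32a1, the transporter that loads GABA into synaptic vesicles, fell from 131.2 ± 6.74 to 3.998 ± 1.17 CPM, a 32.8-fold drop (adjusted p = 1.02e-06). The GABA-synthesising enzymes fell too, Gad1 from 369.0 ± 6.44 to 151.8 ± 4.61 CPM and Gad2 from 654.4 ± 39.6 to 242.2 ± 6.08 CPM, or 2.43-fold and 2.70-fold. Abat, which degrades GABA, fell 1.32-fold. Slc6a11, a GABA transporter of the plasma membrane, was at 46.4 ± 5.25 and 46.3 ± 6.68 CPM with adjusted p = 0.974. Thus 5 of 6 tested members of this list fell and 0 rose, over all genes and adjusted over the list alone (median log2 fold change −0.84, camera adjusted p = 6.66e-05; adjusted p = 0.0761 with an estimated correlation).

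**Figure D1:**
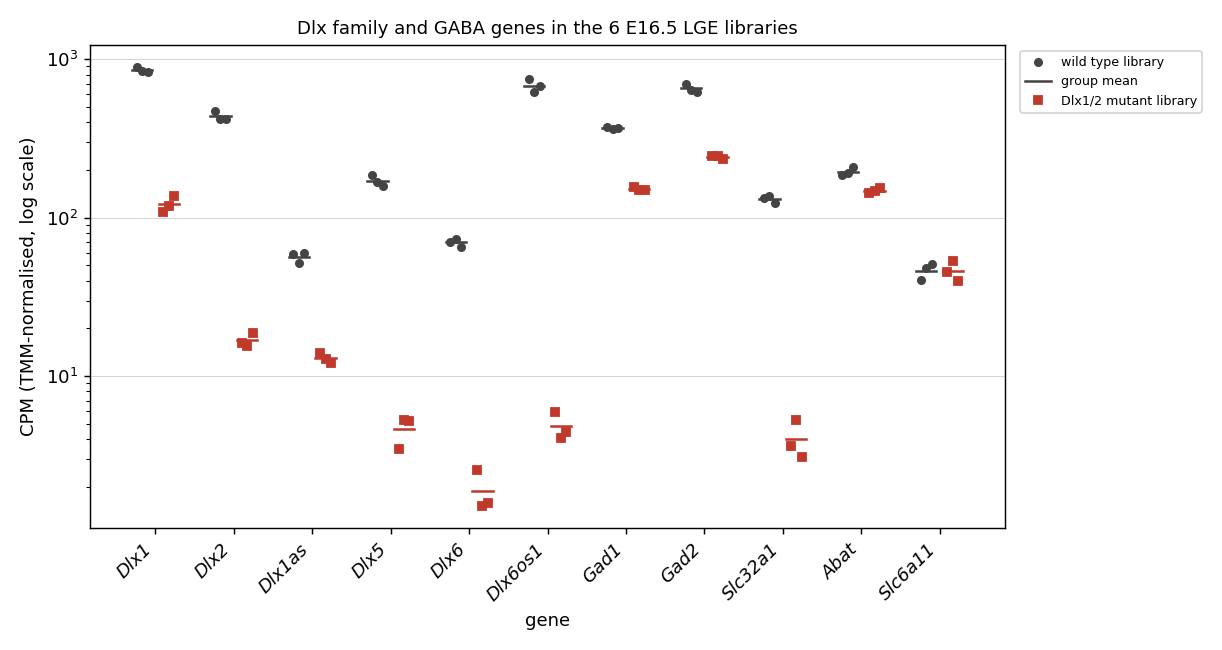
Levels of the Dlx family and of GABA genes in each library, as TMM-normalised CPM on a log axis, with 3 wild type libraries (circles), 3 Dlx1/2 mutant libraries (squares) and the group means (lines). Mutant libraries lie below wild type libraries for each gene but Slc6a11, whose means are 46.4 and 46.3 CPM.

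Most transcription factors and markers of olfactory bulb interneurons were lower in the mutant, but not all of them. Meis2, a homeobox factor, fell from 907.8 ± 28.9 to 319.4 ± 19.98 CPM (log2 fold change −1.51 ± 0.059). Sp8, a zinc finger factor of these neurons, fell 2.70-fold, Etv1 from 46.9 ± 20.5 to 11.2 ± 0.518 CPM and Vax1 from 22.4 ± 1.45 to 8.79 ± 0.557 CPM. Th, the enzyme of dopamine synthesis, was rare and fell from 3.33 ± 1.012 to 0.167 ± 0.239 CPM (log2 fold change −4.278, or −6.428 without mutant replicate 3). Sp9, the close relative of Sp8, was at 320.0 ± 21.1 and 289.7 ± 30.0 CPM with adjusted p = 0.254. The opposite change was seen in Sall3, a zinc finger factor, which rose from 74.0 ± 2.55 to 224.1 ± 7.07 CPM, and in the nuclear receptor Nr4a2, which rose from 2.74 ± 1.10 to 19.1 ± 2.51 CPM. Of 14 tested members, 9 fell, 2 rose and 3 did not pass the test; adjusted over the list alone, 10 fell and 3 rose. The list was lower as a whole (median −0.95, camera adjusted p = 0.00139; adjusted p = 0.0788 with an estimated correlation). Without the members that stand in another list too, its median was −0.387 and its adjusted p = 0.321.

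Genes of striatal projection neurons, the other main neuron class of the LGE, were lower too. Among markers shared by both striatal output pathways, Rarb, a retinoic acid receptor, fell from 126.8 ± 3.77 to 5.51 ± 0.629 CPM. Ppp1r1b, the phosphoprotein DARPP-32, fell 24.2-fold and the zinc finger factor Ikzf1 from 49.4 ± 6.17 to 3.64 ± 0.201 CPM. Foxp1 fell from 207.3 ± 11.02 to 35.9 ± 12.7 CPM, and Bcl11b, which encodes Ctip2, 2.06-fold from 1183 ± 16.8 to 573.0 ± 12.9 CPM. Of 22 tested members, 17 fell, 0 rose and 5 did not pass the test, with the same counts adjusted over the list alone (median −1.95, camera adjusted p = 4.76e-11; adjusted p = 0.0541 with an estimated correlation). Adcy5, an adenylyl cyclase of the striatum, was among those 5 at 41.0 ± 4.10 and 45.2 ± 1.67 CPM.

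Both striatal output pathways lost markers. In the direct pathway list, the dopamine receptor Drd1 fell from 19.9 ± 2.96 to 0.643 ± 0.083 CPM, the substance P precursor Tac1 from 48.2 ± 7.38 to 3.34 ± 0.376 CPM and Ebf1 from 318.2 ± 9.83 to 46.6 ± 4.82 CPM. Isl1, a LIM homeobox factor of this lineage, fell by only 0.54 on the log2 scale (adjusted p = 0.00131). In the indirect pathway list, Drd2 fell from 23.8 ± 2.24 to 3.65 ± 0.820 CPM, the adenosine receptor gene Adora2a from 34.1 ± 4.81 to 5.16 ± 0.515 CPM and the glutamate receptor subunit gene Grik3 from 386.0 ± 31.7 to 118.7 ± 9.96 CPM. The direct list had 8 of 10 tested members lower (median −1.74, camera adjusted p = 1.66e-06; adjusted p = 0.0541 with an estimated correlation). The indirect list had 6 of 9 lower (median −1.50, camera adjusted p = 1.53e-05; adjusted p = 0.0761 with an estimated correlation). No member of either list rose, and both counts stayed as they were when adjusted over the list alone.

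**Figure D2:**
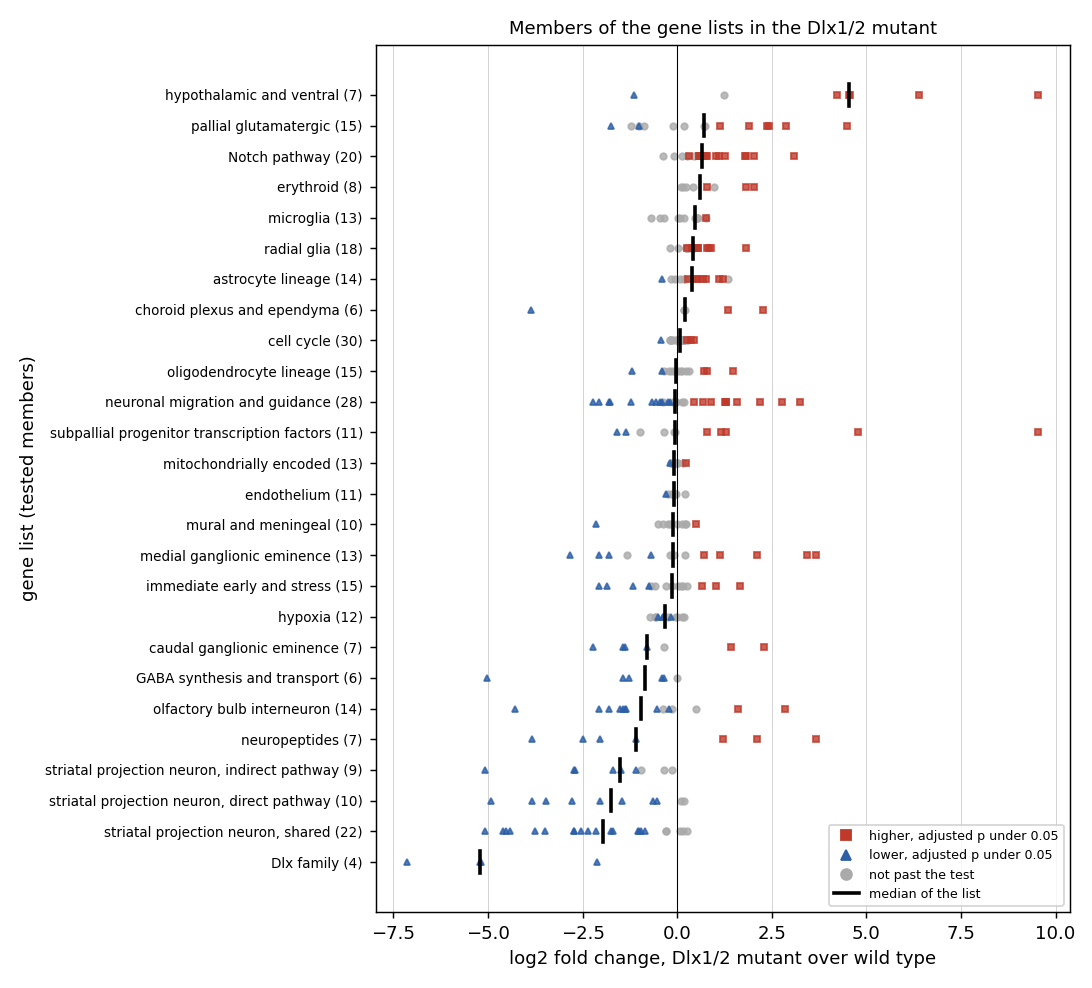
Log2 fold change (mutant over wild type) of each tested member of the gene lists, 1 list per line with its number of tested members, sorted by the list median (black bar). Squares are members higher and triangles members lower at adjusted p below 0.05, and circles did not pass the test; the sex-linked list is left out, and so are Dlx1 and Dlx2. The Dlx family and the 3 striatal lists lie to the left with medians of −5.20 to −1.50. The hypothalamic and ventral list lies to the right with a median of 4.53 over the 7 of its 15 entries that were tested.

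Genes of the Notch pathway, through which neighbouring progenitors hold each other back from differentiation, were higher in the mutant. The ligand genes Dll1 and Dll3 rose, Dll1 from 70.3 ± 5.93 to 244.7 ± 10.7 CPM and Dll3 from 33.7 ± 1.60 to 136.4 ± 11.4 CPM. The target gene Hes5 rose from 33.6 ± 3.43 to 118.1 ± 8.11 CPM. Id2, an inhibitor of basic helix-loop-helix factors that the list also held, rose from 9.80 ± 0.859 to 83.7 ± 8.88 CPM. Of 20 tested members, 15 rose, 0 fell and 5 did not pass the test, and 16 rose adjusted over the list alone (median 0.66, camera adjusted p = 2.70e-09; adjusted p = 0.0793 with an estimated correlation). Among radial glia markers, Sox9 rose from 94.5 ± 2.44 to 174.2 ± 7.05 CPM, Ptprz1, a receptor phosphatase, from 618.8 ± 33.9 to 1073 ± 35.4 CPM and Ttyh1, a chloride channel gene, from 154.3 ± 8.52 to 225.9 ± 12.4 CPM. In that list 10 of 18 rose and 0 fell, while 14 rose and 1 fell adjusted over the list alone (median 0.42, camera adjusted p = 1.53e-05; adjusted p = 0.182 with an estimated correlation). Hes5 stands in both lists.

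Cell cycle genes as a list did not pass the test. Of 30 tested, 3 rose, 1 fell and 26 did not pass, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.238). E2f1, a transcription factor of S phase entry, rose from 37.7 ± 1.70 to 51.1 ± 1.57 CPM, and the cyclin gene Ccnd2 fell from 1298 ± 140 to 963.8 ± 30.6 CPM. Without wild type replicate 1 the list was called higher (median 0.191, adjusted p = 0.00218).

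Transcription factors of subpallial progenitors split in direction. Gsx1, a homeobox factor of ganglionic eminence progenitors, rose from 7.23 ± 0.066 to 199.0 ± 18.8 CPM, a 27.5-fold rise. Vax1 fell from 22.4 ± 1.45 to 8.79 ± 0.557 CPM. Of 11 tested members, 5 rose, 2 fell and 4 did not pass; adjusted over the list alone, 5 rose and 3 fell. The median was −0.06 while the mean was 1.19, which Otp pulls up, and camera gave adjusted p = 0.164. The rotation test fry, which asks only whether the members move one way on balance, gave adjusted p = 2.71e-04 with an upward sign.

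Several of the genes with large rises encode transcription factors and had few reads in wild type LGE; they were picked by their rise and are no tested group. Otp, a homeobox factor of hypothalamic neurons, rose from 0.558 ± 0.354 to 445.8 ± 31.9 CPM, a log2 fold change of 9.55 ± 0.459 (adjusted p = 1.21e-07; 10.29 without wild type replicate 3). Pax7, a paired box factor of the dorsal midbrain and of muscle stem cells, had 1 read over the wild type group and 1530 over the mutant group, a ratio of 1350 with a 95% counting interval of 242 to 53300. Tfap2b, an AP-2 factor, had 2 and 915 reads (ratio 403, interval 111 to 3340), and Evx2, a homeobox gene beside the Hoxd cluster, had 1 and 385 reads (ratio 339, interval 60.6 to 13400). These intervals cover counting error only. Ebf3 rose from 1.89 ± 0.357 to 156.3 ± 55.5 CPM, Tal2, a helix-loop-helix factor of midbrain GABA neurons, from 0.359 to 13.0 CPM (log2 fold change 5.353, or 6.305 without wild type replicate 1), and the LIM homeobox factor Lhx9 from 0.630 ± 0.125 to 14.9 ± 2.45 CPM. Among other large rises, Robo3, an axon guidance receptor of commissural neurons, rose by 4.41 on the log2 scale and Mab21l1 from 0.425 to 11.1 CPM.

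**Figure D3:**
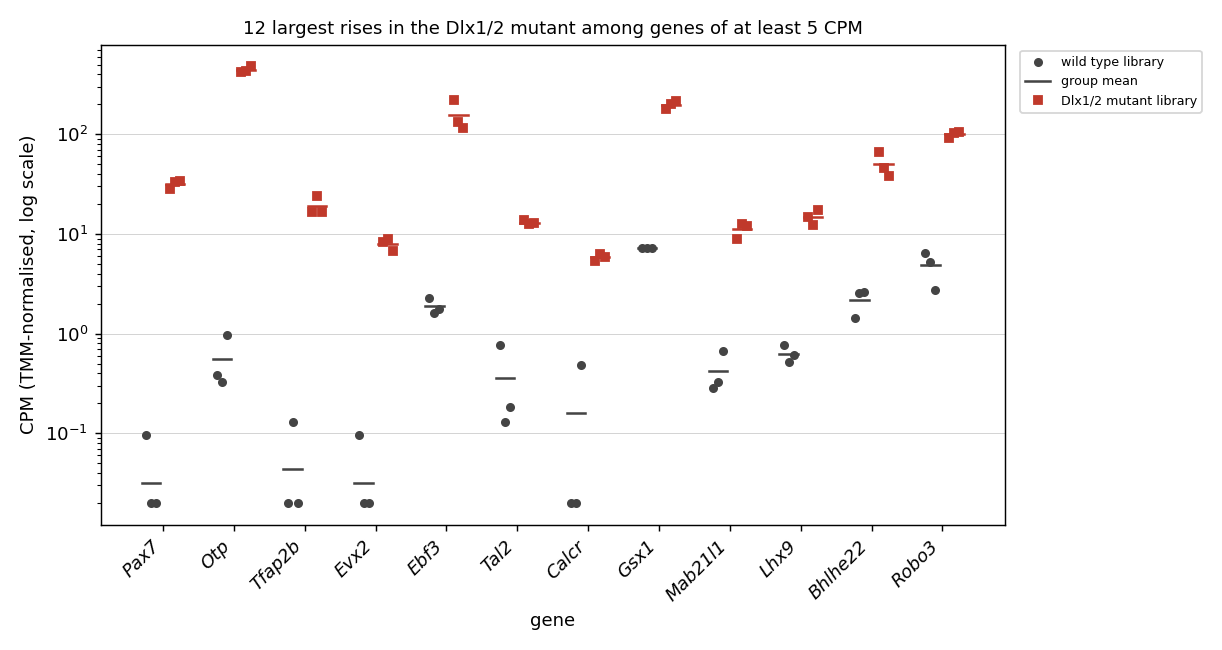
Levels of the 12 genes with the largest rise among called genes with groups apart, at least 5 CPM in the mutant and no clone name, as TMM-normalised CPM on a log axis, per library (circles wild type, squares mutant) with group means as lines. Libraries without a read of the gene are drawn at the lowest level of the plot. For each of these genes the 3 mutant libraries lie above the 3 wild type libraries, as for Otp with means of 0.558 and 445.8 CPM.

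Otp, Ebf3 and Lhx9 belong to the list of hypothalamic and ventral markers, which has 15 entries, 7 of them tested. The other entries had too few reads for the filter or were not found among the genes. Otp and Lhx9, at 0.558 and 0.630 CPM in wild type, passed the filter by their mutant reads. Counts and median of this list thus favour members that are high in the mutant. Of the 7 tested members 5 rose, while Pou3f4, a POU factor of the striatum as well, fell from 160.4 ± 14.9 to 73.0 ± 7.41 CPM. Adjusted over the list alone, 6 rose and 1 fell (median 4.53, camera adjusted p = 1.23e-04; adjusted p = 0.0761 with an estimated correlation). With Lhx1 and Lhx5, which had 3 and 2 wild type reads and are named for that reason only, set to the lower end of their counting intervals, the median was 2.83. The list of pallial glutamatergic neurons, the excitatory class of the cortex, did not pass as a whole. Bhlhe22 rose from 2.19 ± 0.653 to 50.5 ± 14.9 CPM and Neurod1 from 2.63 ± 1.20 to 19.8 ± 2.38 CPM, while Mef2c fell from 44.9 ± 3.66 to 13.3 ± 1.31 CPM and Lmo3 from 135.9 ± 9.29 to 67.5 ± 5.30 CPM. Of 15 tested, 6 rose, 2 fell and 7 did not pass; adjusted over the list alone, 6 rose and 3 fell (median 0.70, camera adjusted p = 0.238).

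Markers of the other ganglionic eminences moved both ways. In the medial list, the peptide genes Sst and Npy rose from 17.2 ± 3.63 to 222.7 ± 38.0 CPM and from 23.9 ± 1.67 to 102.5 ± 12.8 CPM, while the transcription factor Maf fell from 63.0 ± 3.10 to 14.9 ± 1.65 CPM. There 5 of 13 rose and 4 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.591). In the caudal list, the nuclear receptor Nr2f1 rose from 97.6 ± 19.3 to 479.2 ± 6.04 CPM and the homeobox factor Prox1 from 49.8 ± 8.67 to 134.4 ± 8.71 CPM, while Reln, a secreted guidance protein, fell from 116.1 ± 8.23 to 24.7 ± 4.36 CPM. There 2 of 7 rose and 4 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.238; fry adjusted p = 0.0101). Neuropeptide genes parted in the same manner, with Sst and Npy higher and Tac1 and Pdyn lower; in all, 3 rose and 4 fell of 7, over all genes and adjusted over the list alone (camera adjusted p = 0.868).

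Among genes of neuronal migration and guidance, 10 of 28 rose and 11 fell. Pak3, a kinase of the cytoskeleton, rose from 199.1 ± 17.1 to 904.8 ± 30.6 CPM, Nrp2, a semaphorin receptor, from 9.46 ± 1.68 to 90.5 ± 10.1 CPM and Slit1 from 146.1 ± 5.97 to 354.6 ± 18.8 CPM. The Slit receptor gene Robo2 fell from 350.0 ± 15.1 to 84.0 ± 5.62 CPM. Adjusted over the list alone, 10 rose and 13 fell. The median was −0.06 and the mean 0.13, and camera gave adjusted p = 0.978 with a downward sign, whereas fry gave adjusted p = 0.0339 with an upward sign.

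Markers of other cell types in the dissected tissue were tested as measured facts beside these groups. The astrocyte lineage list was higher in the mutant, with 7 of 14 up and 1 down, or 8 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 0.00638; adjusted p = 0.375 with an estimated correlation). The members that rose most clearly were Nfia, from 59.9 ± 2.28 to 139.0 ± 13.6 CPM, Nfib and Nfix, nuclear factor I genes that radial glia and neurons also use. Red blood cell genes were higher, with 3 of 8 up and 0 down, also adjusted over the list alone (median 0.59, camera adjusted p = 0.0260; adjusted p = 0.484 with an estimated correlation). The beta globin gene Hbb-bt rose from 55.3 ± 7.51 to 94.3 ± 12.6 CPM, though reads of near-identical globin copies are uncertain. The call of the red blood cell list was lost without wild type replicate 1 (camera adjusted p = 0.0604), wild type replicate 3 (0.0581) or mutant replicate 3 (0.0647).

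Of 15 tested oligodendrocyte lineage genes 3 rose and 2 fell, also adjusted over the list alone, with Olig2 rising from 41.0 ± 5.26 to 70.5 ± 5.88 CPM and Sox8, which early striatal cells also express, falling from 186.4 ± 8.53 to 81.4 ± 5.17 CPM (camera adjusted p = 0.616). Of 13 microglia genes 1 rose, or 6 adjusted over the list alone (camera adjusted p = 0.132; fry adjusted p = 0.0346). Of 11 endothelial genes 1 fell and 0 rose, or 0 and 0 adjusted over the list alone (median −0.08, camera adjusted p = 0.238). Mural and meningeal genes had 1 of 10 up, the receptor gene Pdgfrb, and 1 down, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.616). Of 6 genes of choroid plexus and ependyma 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.238; fry adjusted p = 0.0201). The homeobox gene Otx2 rose from 6.51 ± 1.39 to 31.2 ± 3.24 CPM.

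Among lists of sample quality, hypoxia genes were lower, with 4 of 12 down and 0 up, or 6 and 0 adjusted over the list alone (median −0.31, camera adjusted p = 0.0366; adjusted p = 0.484 with an estimated correlation). Ldha, lactate dehydrogenase, fell from 185.7 ± 13.4 to 130.4 ± 1.42 CPM and the glucose transporter gene Slc2a1 from 77.5 ± 4.31 to 59.4 ± 2.10 CPM. The call of the list was lost without wild type replicate 3 (adjusted p = 0.0581) or mutant replicate 3 (0.162). Immediate early and stress genes went both ways, with 3 of 15 up and 4 down, also adjusted over the list alone (camera adjusted p = 0.616). Npas4, an activity-induced factor, fell from 15.5 ± 2.90 to 3.70 ± 0.140 CPM, and the antiproliferative gene Btg2 rose from 61.4 ± 6.92 to 192.8 ± 11.7 CPM. Of 13 mitochondrially encoded genes 1 rose and 1 fell, also adjusted over the list alone (median −0.08, camera adjusted p = 0.410). Mitochondrial reads took 1.87% to 2.02% of the counts in each library.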

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

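The thinned libraries and the correction for GC content and length were chosen after the data had been seen. In every alternative run on genes, no called gene changed sign and Dlx1 and Dlx2 stayed past the threshold. The counts of higher and lower genes were 1708 and 1959 under RLE scaling, 1603 and 1903 without the filter, 1578 and 1825 by DESeq2, 1619 and 1750 after thinning, and 1981 and 1977 after the correction. Leaving out a library gave 1211 to 1626 higher and 1416 to 1956 lower genes. Stricter rules call fewer genes by construction: 436 higher and 619 lower with a 2-fold minimum, and 875 and 1116 at adjusted p below 0.01. With the replicate number as a block, 1223 genes were higher and 1458 lower, sharing 71.8% of the calls, and 12 lists were called. Deviations of same-numbered libraries correlated at −0.178, 0.039 and −0.178, so the numbers were not taken to pair the libraries, and none of the 3 wild type libraries correlated best with its own number. Of 122 called genes under the naming rule, 16 lost the call in at least 1 alternative other than the stricter rules and 0 changed sign; these 16 were left out of the text after that was seen, so named genes keep their call in those alternatives by choice. Of 93 called genes named besides the targets, 15 changed by less than 2-fold and so lose the call under that minimum. Slc6a11, not called, had a log2 fold change of 0.09 after thinning and 0.018 after the correction, and of −0.121 to 0.084 with a library left out. Xist, not called either, ran from −7.757 to 9.566 with a library left out, since 1 library of each group holds nearly all of its reads, and DESeq2 gave it no adjusted p. Tbr1 without wild type replicate 1, and Neurog2 in 5 alternatives, were called lower.

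With an estimated correlation 0 lists were called, at the same medians: −1.948 (shared striatal), −1.744 (direct), −1.498 (indirect), −5.202 (Dlx), −0.841 (GABA), −0.948 (olfactory bulb), 0.662 (Notch), 0.417 (radial glia), 4.529 (hypothalamic and ventral), 0.391 (astrocyte), 0.591 (erythroid) and −0.307 (hypoxia). The test with an estimated correlation allows a wider spread, and which correlation is right for these lists was not tested. At the preset correlation, camera called up to 10 lists in a split that mixed the genotypes, with 0 genes called in that split. By fry, the caudal list (−0.807) was called lower, and the choroid (0.2), microglia (0.478) and subpallial (−0.059) lists higher, the last against the sign of its median. The erythroid list (0.591) was not called, and migration genes (−0.062) were called higher, opposite to the sign by camera. Without shared members the olfactory bulb list (−0.387, with fewer members) was not called. With a library left out, the medians of the lists that changed their call ran from −0.002 to 0.191 for cell cycle, 0.462 to 0.695 for erythroid and −0.37 to −0.202 for hypoxia; the cause was not tested. Depth limits rare genes: 3 counts are 0.280 CPM in wild type replicate 1.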

Other observations

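Genes outside the naming rule are named in this part after their values had been seen, and the tests of other chromosomes, of cycling cells, of endothelial and other non-neuronal genes and of pallial tissue were chosen only after the result was seen, as was the use of the odds ratio near Dlx1 for the genes there alone. Alongside Slc32a1, the vesicular monoamine transporter gene Slc18a2 fell from 206.3 ± 23.3 to 17.5 ± 3.58 CPM (edgeR adjusted p = 3.29e-06), and Crabp1, a retinoic acid-binding protein, from 27.8 to 2.14 CPM (adjusted p = 5.14e-06). Egfr, the epidermal growth factor receptor, rose from 27.1 to 123.7 CPM (adjusted p = 8.66e-06). Several more transcription factor genes that were rare in wild type rose. Pax5 went from 1.52 to 10.3 CPM, Tfap2a from 0.201 to 4.50 CPM and Gbx2 from 0.961 to 10.6 CPM, with adjusted p = 6.84e-05, 1.11e-04 and 1.28e-04. Lmx1b had 1 read over the wild type group and 82 over the mutant group, a ratio of 72.3 with a 95% counting interval of 12.6 to 2890. In each of these 7 genes all 3 mutant libraries lay on the same side of all 3 wild type libraries.

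Xist, which is transcribed from an inactive X chromosome, was at 4028 CPM in wild type replicate 1 and 4582 CPM in mutant replicate 3, and at 1.448 to 9.63 CPM in the other 4 libraries. Genes of the Y chromosome together, per library total without TMM scaling, were at 0.3 CPM in each of those 2 libraries and at 296.2 to 360.1 CPM in the others. Each group thus had 1 library high in Xist. Of 5 tested members of the sex-linked list 0 rose and 0 fell (edgeR; camera adjusted p = 0.937), over all genes and adjusted over the list alone.

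The 3673 calls between mutant and wild type were weighed against chance and technical sources. The 6 libraries make 10 splits into 3 and 3, too few for a share below 0.05. The real split called 3673 genes and 12 lists, and of the 10 splits only this 1 reached either number. Among the other splits, the most genes called in any was 3. The most lists called was 10, in the split of wild type replicate 1 with mutant replicates 1 and 3, which called 0 genes. List calls by camera at the preset correlation were thus nearly as many in a regrouping without a called gene. Strain sequence carried along with the targeted alleles could reach genes linked to Dlx1 on chromosome 2. On other chromosomes 3357 of the 14038 tested genes were called too (23.9%), and these are not themselves linked to Dlx1. As the share of calls was known when this test was chosen, its outcome was fixed and it decides nothing further. It does not cover effects of linked sequence on distant genes, or strain differences elsewhere on the mixed background. For chromosome 2, where 298 of 1212 genes besides Dlx1, Dlx2 and Dlx1as were called, linked strain sequence stays open as a source. Within 10 Mb of Dlx1, these 3 left out, 33 of 97 genes were called, Evx2, Gad1 and Neurod1 among them. The planned odds ratio against the rest was 1.64 (Fisher's exact test, two-sided p = 0.0233), with a 95% interval of 1.04 to 2.54, above 1 as linked strain sequence predicts. Transcript length or GC bias and the lower depth of wild type replicate 1 are argued against as sources of most calls, because 96.9% of the calls stayed with the same sign after a correction for both and 87.4% after thinning to the smallest library, while a batch that follows the library names cannot be told apart from genotype, and the loss of Dlx1 and Dlx2 is the biological difference that the design names.

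The fall of the striatal lists and the rise of the Notch list may reflect a change of cell composition. Fewer neurons would lower pan-neuronal genes as much as striatal ones, but 12 pan-neuronal genes had a median log2 fold change of −0.15, from −0.61 (Stmn2) to 0.62 (Elavl4), with 5 called lower and 2 higher, against −1.95 for the shared striatal list (permutation p = 0.02, two-sided). More cycling cells would raise cell cycle genes as much as Notch genes, but their median was 0.08 against 0.66 (permutation p = 1e-05, the smallest that 100000 resamples can give). Without wild type replicate 1 the cell cycle median was 0.191 and the list was called higher (camera adjusted p = 0.00218), so a smaller rise in cycling cells stays open. Fewer neurons would also raise all non-neuronal markers alike, and the erythroid, microglia, astrocyte and choroid plexus lists had medians of 0.59, 0.48, 0.39 and 0.2, which goes with it, but the endothelial median was −0.08, below the Notch list (permutation p = 0.007) and below these 4 lists (p = 8.5e-04, 0.013, 0.015 and 0.043), with mural and oligodendrocyte genes at −0.1 and −0.02 (p = 0.84 and 0.22 against endothelial genes). These permutations shuffled genes, not libraries. They argue against a loss of neurons as deep as the striatal fall, but a smaller loss stays open. A larger share of radial glia was not tested, and that list had 10 of 18 members higher and 0 lower (median 0.42). Also open are a change within the neurons and progenitors themselves, a shift between neuron classes, or a difference in dissection.

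The transcription factor genes that had few reads in wild type and rose in the mutant may come from tissue outside the LGE. Pallial tissue would bring Tbr1, Eomes and Neurog2, whose log2 fold changes were −0.89 ± 0.625, −1.01 ± 0.764 and −1.23 ± 0.532 (SE), although Neurod2 and Neurod6 rose from 11.1 to 58.6 and from 8.05 to 44.6 CPM. Hypothalamic tissue would bring other hypothalamic genes with Otp, but 7 of them (Sim1, Nr5a1, Fezf1, Hmx2, Hmx3, Pomc and Oxt) summed to 2.68 ± 0.260 CPM in the mutant, 0.6% of the rise of Otp, against 0.827 ± 0.234 CPM in wild type. Sim1 and Hmx3 were at 0.745 and 0.356 CPM in the mutant and at 0.042 and 0 CPM in wild type. This compares the sum with Otp alone. Lhx1, Lhx5 and Lmx1b were at 1.476, 1.269 and 1.706 CPM in the mutant, each below the sum. Hypothalamic tissue thus stays open as a source of such rare factors. Tissue of other regions, such as midbrain, was not tested. A hypothesis left open is that cells of the mutant LGE themselves turned on these genes, which tissue RNA does not locate.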
